A study of Homo sapiens with 12 samples.

How the data were processed

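Total RNA was sequenced from human myotubes, multinucleate muscle cells made in culture by differentiating an induced pluripotent stem cell line. Per the labels, the cells carried a vector for mCherry, a red fluorescent protein that serves as the control, or a vector for MAFA, MAFB or MAF, the large MAF transcription factors. The labels give 3 libraries for each of the 4 groups, 12 in all. Per the labels' protocols, RNA was taken on day 4 of infection, and the series' design text names day 6 of differentiation. Ribosomal RNA was depleted and strand-specific libraries were prepared, per the labels' protocols. Nothing in the labels says whether libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

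The authors deposited whole-number read counts per gene, per the file headers' expression-value columns, for 57773 features named by gene symbol. The genome build was hg19, per the submitters' processing notes. The aligner, the counting program and its strand setting, and the gene annotation are not given in the sources used here, so reads of overlapping, antisense or near-identical genes could have been split between them. The same deposited table holds quantile-normalised values, a signal that the authors derived from those counts, per the file headers. On every rank these values equalled the mean of the sorted counts of the 12 libraries, and each library summed to 7281063. The authors' transformed values were log2 of the quantile-normalised value plus 1, checked on the table. Quantile normalisation gives every library 1 distribution, which removes differences in depth and also any true difference in the overall distribution. The 12 columns of group means in the table were not used.

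The analysis began from the counts, with edgeR 4.0.16 in R 4.3.3. The plan made before the data were examined named limma on the quantile-normalised values and, if the table held whole-number counts, edgeR's quasi-likelihood test in its place. The table held counts, so the second applied and limma 3.58.1 became an alternative. Genes were kept with filterByExpr at a minimum count of 10 and a minimum total of 15, which left 13860 of the 24673 features that had a count in at least 1 library. Libraries were scaled by TMM, and normalised counts are given as CPM, each count relative to its scaled library size. All 12 libraries entered 1 fit with group means only. Each pair of groups was compared, an F test covered the 3 contrasts with the control, and p-values were adjusted by the Benjamini-Hochberg method over the 13860 genes. The threshold was an adjusted p of 0.05. A standard error (SE) is the log2 fold change divided by the square root of its F statistic. In the same steps on simulated counts for the MAFA comparison, with 200 of 13860 genes changed, edgeR recovered 68.7% of the genes changed by 1.5-fold, 82.1% at 2-fold and 100% at 4-fold, and 6.18% of its calls were false.

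Gene lists, 31 in all, were fixed before the data were examined. They covered the delivered factors and other MAF family genes, muscle contractile, structural and junction genes, metabolism, stress, the cell cycle, interferon response, known targets of MAF factors in lens, islet and macrophage, and markers of other cell types. Lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. The lists overlap in part, so their tests are not independent. Named genes were chosen by a rule made at the same time. It took the delivered factors and sarcomeric myosin heavy chains whatever their values. It then took, among genes past the threshold whose libraries all lay outside the range of the other group, the 8 largest rises and 5 largest falls against the control, or 4 in each direction between factors. This part left out symbols for unnamed loci, several classes of non-coding RNA, and XIST and Y-linked genes. Against the control it also took, for each list, up to 3 of the largest rises and 2 of the largest falls among members past the threshold, or at most the most highly expressed member where none was past it. Where that gave more than about 30 genes, lists with the smaller camera p came first.

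Depth ran from 6424833 to 7759812 counts per library, and from 18662 to 19067 features had a count. The 10 most abundant genes held 8.32% to 8.85% of the counts, and TMM factors lay between 0.9926 and 1.0048. A gene at 1 CPM therefore rests on about 7 counts per library. A ratio against a group with no count in any library is given as a lower bound against 3 counts over the group, and a ratio against 1 to 3 counts with an exact binomial 95% interval. Both cover counting error only, and the lower bound covers only that of the group without a count. No 2 libraries of a group agreed within sampling noise, since the lowest chi-square per degree of freedom was 1.508. Gene order near MYH4 came from RefSeq (GRCh38.p14), which is not the build of the counts, so no coordinates are given.

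Alternatives were limma on the quantile-normalised values with pseudocounts of 1, 0.1 and 10, without a trend and with robust moderation, edgeR without TMM, with DESeq2 size factors and with robust moderation, DESeq2 1.42.0, no filter, a minimum count of 50, a replicate block, only the groups compared, a 2-fold threshold and the removal of each library in turn. Overlaps between comparisons that share the control libraries were set against 20 simulated data sets in which no group differed.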

Results

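Human myotubes made from induced pluripotent stem cells received mCherry, MAFA, MAFB or MAF, and RNA was sequenced in 3 libraries per group, 12 in all. MAFA, MAFB and MAF are the large MAF proteins, basic leucine zipper transcription factors. The title of the series names type IIb fibres, the fast-glycolytic muscle fibres that contain the myosin heavy chain encoded by MYH4 and that human limb muscle hardly uses. Total counts averaged 7331702 ± 263556 in the control, 7285168 ± 48429 with MAFA, 7208384 ± 685584 with MAFB and 7298996 ± 399372 with MAF (SD, n = 3). Levels are given in CPM, counts normalised to library size, as mean ± SD over the 3 libraries of a group. Fold changes are on the log2 scale with their standard error (SE). Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named, and a gene is said to rise or fall only at an adjusted p under 0.05. The first principal component held 39.8% of the variance and put the control libraries between -36.59 and -32.59, with the MAF factor libraries between -1.28 and 28.38. The second, with 12.3%, put the MAFA libraries between -21.53 and -18.31 and the MAFB and MAF libraries between 7.96 and 10.96.

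Each delivered gene was highest in the group that received it. MAFA reached 369 ± 42.6 CPM in its group against 1.59 ± 0.622 CPM in the control (log2 fold change 7.84, SE 0.14, adjusted p = 2.05e-17). MAFB reached 389.9 ± 49.9 CPM against 40.2 ± 1.58 CPM (log2 fold change 3.28, SE 0.10, adjusted p = 6.23e-13), and MAF 649 ± 94.9 CPM against 141 ± 7.23 CPM (log2 fold change 2.20, SE 0.08, adjusted p = 6.86e-13). Control myotubes already held MAF and MAFB transcripts. In the MAF group MAFB also rose, to 60.3 ± 10.7 CPM (log2 fold change 0.59, SE 0.12, adjusted p = 0.000939). MAFA in the MAF group was 3.11 ± 0.404 CPM (adjusted p = 0.0406), a call that ended without control library 1 (adjusted p = 0.13), control library 2 (0.138), MAF library 1 (0.0785) or MAF library 2 (0.136). MAF in the MAFA group was 117 ± 1.37 CPM (log2 fold change -0.27, adjusted p = 0.0192), which ended without control library 1 (adjusted p = 0.0726), control library 3 (0.0648), MAFA library 2 (0.0557) or MAFA library 3 (0.0505) and in limma without a trend and robust edgeR, with an adjusted p of up to 0.0784 over the alternatives. MAFB in the MAFA group had a log2 fold change of -0.30 (adjusted p = 0.116, and from 0.0015 to 0.0353 in 3 limma settings, with no filter and with only the groups compared). MAF in the MAFB group was at -0.24 (adjusted p = 0.0579, and from 0.000149 to 0.0481 in 2 limma settings, with no filter and with only the groups compared), and MAFA there at 0.17 (adjusted p = 0.842).

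The first comparison asked what MAFA changed relative to mCherry. SPP1, which encodes the secreted phosphoprotein osteopontin, rose 66.9-fold, from 3.43 ± 0.366 to 231 ± 11.9 CPM (log2 fold change 6.06, SE 0.08, adjusted p = 9.13e-19). CILP, a cartilage matrix gene, rose 27.7-fold to 108 ± 10.2 CPM, and DHRS2, a short-chain dehydrogenase gene, 22.9-fold to 11.9 ± 4.23 CPM. MYH4 rose from 0.358 ± 0.31 to 4.66 ± 1.81 CPM (log2 fold change 3.61, SE 0.53, adjusted p = 4.84e-05), while the other adult fast myosins, MYH1 and MYH2, fell. Of the fixed lists, 8 of 10 slow-fibre, 7 of 8 embryonic muscle, 11 of 18 structural, 8 of 10 neuromuscular junction, 11 of 20 cell cycle and 6 of 8 neuronal genes fell. With an estimated correlation the camera calls of the cell cycle and neuronal lists held, and those of the 4 muscle lists did not (adjusted p from 0.0916 to 0.276). In all, 3705 of 13860 genes (26.7%) passed the threshold, 1937 higher and 1768 lower, and 424 of them changed at least 2-fold. The MAFA libraries all lay above or all below the control libraries in 5421 of the 13860 genes, which chance gives for 10% of genes.

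Among the largest rises with MAFA, CRYBB1, a lens beta-crystallin gene, had 52 counts in the MAFA libraries against 1 in the control libraries, a ratio of 51.9 with a counting interval from 8.92 to 2090. Its fitted log2 fold change moved from 5.25 to 7.12 without control library 2. ENTPD3 and VIT had no count in the control libraries and were at least 11.3-fold and at least 9.32-fold higher. Among the largest falls were MYL3, a light chain of slow and ventricular myosin (log2 fold change -2.63, SE 0.26, adjusted p = 5.81e-07), the transcription factor gene ONECUT2 (-2.51, SE 0.18, adjusted p = 1.27e-08) and IGSF22 (-2.56, SE 0.52, adjusted p = 0.00109).

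The myosin heavy chains moved apart under MAFA. MYH1, of type IIx fibres, fell by 1.58 on the log2 scale (SE 0.26, adjusted p = 0.000148) and MYH2, of type IIa fibres, fell by 0.71 (SE 0.07, adjusted p = 8.42e-07). The adult fast list held 1 rise and 2 falls among 3 measured genes, with the same counts adjusted over the list alone (camera, adjusted p = 0.371). MYH3, the embryonic heavy chain and the most abundant in these cells, went from 11220 ± 808 to 6652 ± 1210 CPM, and MYH7, of slow fibres, from 518 ± 56.7 to 196 ± 46 CPM. Of the other sarcomeric myosin heavy chains 4 of 6 measured genes fell, also adjusted over the list alone (camera, adjusted p = 6.51e-05, and adjusted p = 0.176 with an estimated correlation). MYH8, the perinatal heavy chain, had a log2 fold change of -0.11 (adjusted p = 0.476). These genes are close to identical in sequence, so the authors' counting could have moved reads between them and single myosin values are uncertain.

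Slow-fibre contractile genes fell in 8 of 10 measured members, and adjusted over the list alone 9 were lower and 1 higher (camera, adjusted p = 1.09e-14, and adjusted p = 0.0916 with an estimated correlation). Embryonic muscle genes fell in 7 of 8 members, also adjusted over the list alone (camera, adjusted p = 1.18e-06, and adjusted p = 0.276 with an estimated correlation). The list of fusion and mature muscle structure fell in 11 of 18 members, 12 adjusted over the list alone (camera, adjusted p = 7.66e-11, and adjusted p = 0.243 with an estimated correlation). ACTA1, the skeletal alpha-actin gene, went from 509 ± 10.4 to 197 ± 9.32 CPM (log2 fold change -1.37, SE 0.04, adjusted p = 3.73e-13). Excitation-contraction coupling genes fell in 9 of 14 members, also adjusted over the list alone (camera, adjusted p = 0.000255, and adjusted p = 0.393 with an estimated correlation), among them the calcium channel subunit gene CACNB1 (log2 fold change -0.76). Without MAFA library 2, 5 of them fell. Neuromuscular junction genes fell in 8 of 10 members, also adjusted over the list alone (camera, adjusted p = 7.79e-07, and adjusted p = 0.176 with an estimated correlation), with CHRNG, the fetal subunit of the acetylcholine receptor, at -0.89 and LRP4, the agrin receptor, at -0.96. The fast-fibre contractile genes did not share a direction. Of 11 measured, 6 rose and 5 fell, also adjusted over the list alone (camera, adjusted p = 0.533). That test passed with the replicate block. MYOZ1 (log2 fold change 1.18) and MYBPC2 (1.04) were among the rises, and MYOM2 (-1.09) and TNNI2 (-0.93) among the falls. Of 21 myogenic and fibre-type regulators 3 rose and 6 fell, 3 and 7 adjusted over the list alone (camera, adjusted p = 0.195). PROX1, a homeobox gene of slow muscle and lens, rose (1.17, SE 0.10), while VGLL2 (-0.86, SE 0.13) and MYOD1 (-0.69, SE 0.07) fell.

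Metabolic lists changed in both directions under MAFA. Of 29 glycolysis and glycogen genes 11 rose and 6 fell, 11 and 7 adjusted over the list alone (camera, adjusted p = 0.408). The phosphorylase kinase subunit gene PHKA1 rose 2.28-fold and PFKFB3 1.47-fold, while ENO3, the muscle enolase, fell by 0.64 on the log2 scale. Of 26 genes of the TCA cycle and respiratory chain 4 rose, among them ACO2 and FH, and 3 fell, 4 and 4 adjusted over the list alone (camera, adjusted p = 0.719). Its falls numbered 0 without control library 3 and 1 without MAFA library 2 or 3. Of 17 genes of fatty acid oxidation and its regulators 5 rose, ACADM and CPT2 among them, and 1, the fatty acid carrier CD36, fell by 1.07, with the same counts adjusted over the list alone (camera, adjusted p = 0.589). Of these, 3 rose without control library 3. Cell cycle genes fell in 11 of 20 members, 15 adjusted over the list alone (camera, adjusted p = 1.62e-05, and adjusted p = 0.0219 with an estimated correlation), such as TOP2A (log2 fold change -0.69) and CDK1 (-0.79).

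Stress lists were mixed. Of 16 unfolded protein and amino acid stress genes 1 rose and 6 fell, also adjusted over the list alone (camera, adjusted p = 0.0543). That test passed without control library 3 (adjusted p = 0.0355) or MAFA library 2 (0.019), in DESeq2 (0.0326), with no filter (0.00803) and with the replicate block. SDF2L1 (log2 fold change -0.85) and HSP90B1 (-0.30) were among its falls. Its rise was lost without control library 1 or 3 or MAFA library 2. HMOX1, heme oxygenase, rose from 11.5 ± 1.82 to 61 ± 7.7 CPM (log2 fold change 2.41, SE 0.14, adjusted p = 1.85e-09), while NQO1, another NRF2 target, fell by 0.54. Of 11 antioxidant NRF2 targets 3 rose and 2 fell, and of 12 p53 targets 3 rose and 3 fell, in both lists with the same counts adjusted over the list alone (camera, adjusted p = 0.533 for each). Of 15 atrophy and autophagy genes 6 rose and 4 fell, 7 and 4 adjusted over the list alone (camera, adjusted p = 0.647), with CTSL at 0.63 and the muscle ubiquitin ligase FBXO32 at -0.86. Interferon response genes rose in 3 of 19 members, also adjusted over the list alone (camera, adjusted p = 0.211, and 0.035 with no filter), MX1 by 1.01 and STAT2 by 0.43. Of this list 5 rose without MAFA library 1.

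Markers of other cell types and tissues also moved under MAFA. Neuronal genes fell in 6 of 8 measured members, also adjusted over the list alone (camera, adjusted p = 1.1e-05, and adjusted p = 0.0161 with an estimated correlation), such as GAP43 (log2 fold change -1.60) and STMN2 (-1.67). Of 7 smooth muscle genes 2 rose and 4 fell, 2 and 5 adjusted over the list alone (camera, adjusted p = 0.108, 0.0418 without MAFA library 2 and 0.0344 with no filter), with LMOD1 at 0.76 and MYH11 at -1.88. Only 1 rose without control library 1 or MAFA library 2 or 3. Of 12 fibroblast and matrix genes 4 rose and 3 fell, 4 and 4 adjusted over the list alone (camera, adjusted p = 0.82), the falls including DCN (-0.46) and LUM (-0.66). The rises numbered 2 without control library 1 or MAFA library 2. Of 6 measured macrophage genes 3 rose, SLC40A1, MERTK and CD68, and 1 fell, F13A1 (-2.18), also adjusted over the list alone (camera, adjusted p = 0.533). CD68 rested on 19 counts against 2, a ratio of 9.49 with an interval from 2.29 to 84. Of 4 measured lens crystallins 1 rose and 1 fell, also adjusted over the list alone (camera, adjusted p = 0.533). The fall, of CRYAB, ended without control library 1 (adjusted p = 0.155), 2 (0.0542) or 3 (0.0519) or MAFA library 2 (0.197). MATN3 (1.03) was the 1 of 6 chondrocyte genes that rose, also adjusted over the list alone (camera, adjusted p = 0.647). In that list 2 rose without MAFA library 1. Of 3 other MAF family genes 1 was higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.979), and over all genes the nearest, MAFG, had a log2 fold change of -0.22 (adjusted p = 0.0571, and from 0.0399 to 0.0488 in the limma settings and with the stricter filter). The lists with 1 or 2 measured members were not tested as sets. Of those, 1 of 2 Schwann and glial genes rose, FABP7, which ended without control library 1 (adjusted p = 0.116), control library 3 (0.0648) or MAFA library 2 (0.158) and moved from 2.26 to 2.88 without control library 2. In the endothelial list 1 of 2 rose, ERG, which ended without control library 1 (adjusted p = 0.109), control library 2 (0.0923), MAFA library 2 (0.152) or MAFA library 3 (0.0567) and in 3 limma settings and DESeq2 (from 0.0578 to 0.0874). Adjusted over the list alone the same single genes rose. In the cardiac list 1 of 2 fell, MYH6, and 2 adjusted over the list alone. The 2 pancreatic islet genes, of which SLC30A8 had a log2 fold change of -0.49 (adjusted p = 0.401), and the 1 pluripotency gene, DNMT3B (0.31, adjusted p = 0.194), did not pass, also adjusted over the list alone.

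The median, the mean and the camera test differed in sign for 5 lists under MAFA. The median log2 fold change, the mean and the direction of the test were -0.27, 2.42 and up for the delivered factors, -0.71, 0.44 and down for the adult fast myosins, and 0.32, 0.15 and down for the fast-fibre genes. They were -0.01, -0.00 and up for the TCA cycle list and -0.04, 0.17 and up for the NRF2 targets. The delivered factors, with 1 rise and 1 fall of 3 and no fall without control library 1 or 3 or MAFA library 2 or 3, 1 and 2 adjusted over the list alone, had an adjusted camera p of 5.25e-13, and an adjusted p = 0.0121 with an estimated correlation, but did not pass in the limma settings or with no filter (adjusted p from 0.338 to 0.675, and from 0.0544 to 0.156 for the same list with MAFB). Against the control, the camera calls that held with an estimated correlation were those of the delivered factors and cell cycle with each factor, neuronal genes with MAFA and MAF, and crystallins with MAFB and MAF. Between factors they were those of the crystallins and adult fast myosins for MAFA against MAFB and against MAF, and of neuronal genes and the delivered factors for MAFA against MAFB. In each factor group the vector supplied 1 of the delivered factors, so calls of that list follow from the design. The filter kept the crystallin genes CRYBB1 and CRYBA4 only through factor groups where they were high, so the crystallin calls were set in part by it. Camera compares a list with all other genes, whereas fry asks only whether the genes of a list move, on balance, in 1 direction.

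The second comparison asked what MAFB changed. MYH4 rose from 0.358 ± 0.31 to 41.8 ± 4.25 CPM (log2 fold change 6.77, SE 0.32, adjusted p = 1.2e-10). SPP1 rose 129-fold to 443 ± 21.4 CPM (adjusted p = 3.07e-20) and MMP13, the gene of a collagenase of bone and cartilage, 68.9-fold to 134 ± 27.4 CPM (adjusted p = 5.12e-12). Of the fixed lists, 3 of 4 lens crystallins and 12 of 19 interferon response genes rose, while 8 of 10 slow-fibre, 10 of 18 structural and 6 of 20 cell cycle genes fell. With an estimated correlation the camera calls of the crystallins and the cell cycle held, and those of the interferon response (adjusted p = 0.0612), slow-fibre (adjusted p = 0.0612) and structural genes (adjusted p = 0.148) did not. In all, 2161 of 13860 genes (15.6%) passed, 1145 higher and 1016 lower, and 278 changed at least 2-fold. The falls numbered 674 without MAFB library 3 and 650 in DESeq2. The groups did not overlap in 4344 of the 13860 genes, against a chance share of 10%.

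Of 4 measured lens crystallins 3 rose with MAFB, also adjusted over the list alone (camera, adjusted p = 1.34e-13, and adjusted p = 0.00129 with an estimated correlation). CRYBB1 reached 37.3 ± 7.97 CPM, 799 counts against 1 in the control (ratio 807, interval 144 to 31900, and a fitted log2 fold change of 9.21, or 11.08 without control library 2), and CRYBA4, with no control count, was at least 35.4-fold higher. CRYGS went from 1.9 ± 0.78 to 10.6 ± 1.79 CPM. The filter kept CRYBB1 and CRYBA4 only through the factor groups, as their control counts were too low. CRYAA, CRYBA1, CRYBB2, CRYBB3, CRYGC and CRYGD of the same list were not kept and stayed at or below 0.331 CPM in every group. The upward list test was therefore set in part by the filter. AMELX, the enamel matrix gene amelogenin, had 329 counts against 2 (ratio 166, interval 45.6 to 1380), with a fitted log2 fold change of 7.13 that moved to 9.79 without control library 3, and MEPE, a bone and tooth matrix gene, was at least 5.05-fold higher. GRIA2, a subunit of AMPA glutamate receptors, had 204 counts against 2 (ratio 103, interval 28.2 to 857). The largest falls included MYL3 (log2 fold change -2.90, SE 0.27), KRT7 (-2.22, SE 0.47) and CLDN1 (-1.86, SE 0.28). NDP fell by 2.18, a call that ended without MAFB library 3 (log2 fold change -1.71, adjusted p = 0.0556) and moved to -4.00 without MAFB library 1, and GOLGA8O, a member of a multicopy family, is uncertain.

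MYH8 rose with MAFB from 1052 ± 46.9 to 1619 ± 227 CPM (log2 fold change 0.62, SE 0.10, adjusted p = 0.000348). MYH2 (log2 fold change -0.40, SE 0.07), MYH7 (-1.79, SE 0.15), MYH7B (-0.93, SE 0.11) and MYH6 (-1.64, SE 0.23) fell. MYH1 (-0.97, adjusted p = 0.00912) fell too, except in limma without a trend (adjusted p = 0.0737). MYH3 (-0.48, adjusted p = 0.00955) was lost without control library 1 (adjusted p = 0.0508) or MAFB library 2 (0.0551) and in 5 limma settings and robust edgeR, and its adjusted p ran up to 0.262 over the alternatives. The adult fast list, with 1 rise and 2 falls of 3, also adjusted over the list alone, had a median of -0.40, a mean of 1.80 and an upward camera test (adjusted p = 0.00771, and adjusted p = 0.0612 with an estimated correlation) that turned downward in 4 limma settings and did not pass in any limma setting, DESeq2 or no filter (adjusted p from 0.287 to 0.976). Of the 6 other sarcomeric myosins 1 rose, or 2 without control library 1 or MAFB library 1, and 4 fell, 2 and 4 adjusted over the list alone (camera, adjusted p = 0.000973, adjusted p = 0.148 with an estimated correlation, and adjusted p from 0.0589 to 0.0672 in the 5 limma settings).

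Slow-fibre genes fell in 8 of 10 members, also adjusted over the list alone (camera, adjusted p = 7e-14, and adjusted p = 0.0612 with an estimated correlation). Genes of fusion and mature structure fell in 10 of 18, 11 adjusted over the list alone (camera, adjusted p = 5.21e-11, and adjusted p = 0.148 with an estimated correlation), ACTA1 2.05-fold. Neuromuscular junction genes fell in 6 of 10, 7 adjusted over the list alone (camera, adjusted p = 0.000151, and adjusted p = 0.194 with an estimated correlation). Of 8 embryonic muscle genes 1 rose and 4 fell, or 7 without MAFB library 1, and 1 and 7 adjusted over the list alone (camera, adjusted p = 0.00771, 0.0693 without MAFB library 2, and adjusted p = 0.454 with an estimated correlation). Of 11 fast-fibre genes 4 rose and 5 fell, 6 and 5 adjusted over the list alone (camera, adjusted p = 0.648). ACTN3, the fast-fibre alpha-actinin, rose 5.36-fold to 3.96 ± 1.08 CPM, MYBPC2 2.54-fold and MYOZ1 2.13-fold. Glycolysis and glycogen genes rose in 11 of 29 members and fell in 2, 12 and 2 adjusted over the list alone (camera, adjusted p = 0.0104, and adjusted p = 0.0612 with an estimated correlation). TCA cycle and respiratory chain genes rose in 3 of 26, also adjusted over the list alone (camera, adjusted p = 0.00836, and adjusted p = 0.247 with an estimated correlation). Genes of fatty acid oxidation rose in 4 of 17 and 1 fell, or 0 without control library 1 or 3 or MAFB library 2 or 3, and 5 and 1 adjusted over the list alone (camera, adjusted p = 0.0859, 0.0347 without control library 1, 0.0263 without MAFB library 2, and from 0.0178 to 0.0478 in limma, with no filter and with the stricter filter), and PPARGC1A, a regulator of mitochondrial genes, rose 1.73-fold. Excitation-contraction coupling genes fell in 3 of 14, or 1 without MAFB library 2, and in 3 adjusted over the list alone (camera, adjusted p = 0.0859, 0.0294 without MAFB library 1 and 0.0401 with only the groups compared).

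Interferon response genes rose in 12 of 19 members with MAFB, 15 adjusted over the list alone (camera, adjusted p = 3.05e-10, and adjusted p = 0.0612 with an estimated correlation). MX1 rose 3.52-fold to 19.3 ± 5.11 CPM and OAS1 3.12-fold to 5.4 ± 2.22 CPM. Cell cycle genes fell in 6 of 20, 7 adjusted over the list alone (camera, adjusted p = 1.34e-05, and adjusted p = 0.0199 with an estimated correlation). Of 8 neuronal genes 1 rose, MAP2 (log2 fold change 1.60), and 5 fell, among them DCX (-0.91), also adjusted over the list alone (camera, adjusted p = 0.0205, 0.0564 without MAFB library 2, and adjusted p = 0.0943 with an estimated correlation). Smooth muscle genes fell in 5 of 7, also adjusted over the list alone (camera, adjusted p = 0.00144, and adjusted p = 0.177 with an estimated correlation). Of 6 macrophage genes 3 rose and 1 fell, also adjusted over the list alone (camera, adjusted p = 0.00836, adjusted p = 0.0612 with an estimated correlation, and adjusted p from 0.051 to 0.105 in the limma settings, with no filter and with only the groups compared). SLC40A1, the iron exporter, rose 2.95-fold and F13A1 fell by 1.84 on the log2 scale. Stress genes of the unfolded protein list fell in 5 of 16, or 2 without control library 2 or 3 and 1 without MAFB library 1 or 3, with 1 higher and 6 lower adjusted over the list alone (camera, adjusted p = 0.00849, 0.0909 without MAFB library 1, and adjusted p = 0.248 with an estimated correlation). Of the fibroblast and matrix genes 3 rose and 3 fell, 4 and 3 adjusted over the list alone (camera, adjusted p = 0.893). Only 1 rose without control library 1 or 3, and 1 fell without MAFB library 3. Median, mean and test also differed in sign for the p53 targets (0.04, -0.00 and down) and the NRF2 targets (-0.14, 0.06 and down).

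The third comparison asked what MAF changed. DHRS2 rose from 0.505 ± 0.0924 to 112 ± 30.1 CPM (log2 fold change 7.75, SE 0.41, adjusted p = 1.78e-10), SPP1 166-fold to 574 ± 4.25 CPM and MMP13 from 1.93 ± 0.443 to 197 ± 13.1 CPM. MYH4 rose from 0.358 ± 0.31 to 28.7 ± 5.16 CPM (log2 fold change 6.23, SE 0.35, adjusted p = 2.82e-10). Of the fixed lists, 3 of 4 crystallins rose, while 12 of 18 structural, 9 of 10 slow-fibre, 15 of 20 cell cycle and 6 of 8 neuronal genes fell. With an estimated correlation the camera calls of the crystallins, cell cycle and neuronal genes held, and those of the structural (adjusted p = 0.28) and slow-fibre genes (adjusted p = 0.138) did not. In all, 4393 of 13860 genes (31.7%) passed, 2244 higher and 2149 lower, and 650 changed at least 2-fold. The groups did not overlap in 5994 of the 13860 genes, against a chance share of 10%.

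MEPE, with no control count, was at least 48.8-fold higher with MAF and reached 6.72 ± 0.752 CPM. KL, which encodes klotho, had 191 counts against 1 (ratio 192, interval 34 to 7610, and a fitted log2 fold change of 7.12, or 8.99 without control library 3). CRYBB1 had 601 counts against 1 (ratio 603, interval 108 to 23900, and a fitted log2 fold change of 8.77, or 10.65 without control library 2), CRYBA4 was at least 19.4-fold and VIT at least 10.4-fold higher, and CRYGS rose 11.5-fold to 22.2 ± 1.51 CPM. Of 4 crystallins 3 rose, also adjusted over the list alone (camera, adjusted p = 1.68e-08, and adjusted p = 0.00932 with an estimated correlation). As with MAFB, the filter set this list test in part. FABP7, a fatty acid binding protein of glia, rose 16.1-fold to 5.39 ± 2.56 CPM (log2 fold change 4.01, and 4.64 without control library 2). The largest falls included MYL3 (log2 fold change -2.81, SE 0.27), KRT7 (-2.63, SE 0.50), NDP (-2.58, SE 0.57) and ONECUT2 (-2.45, SE 0.18). CFB_2 appears under a repeated gene name in the deposited table and is uncertain.

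**Figure D1:**
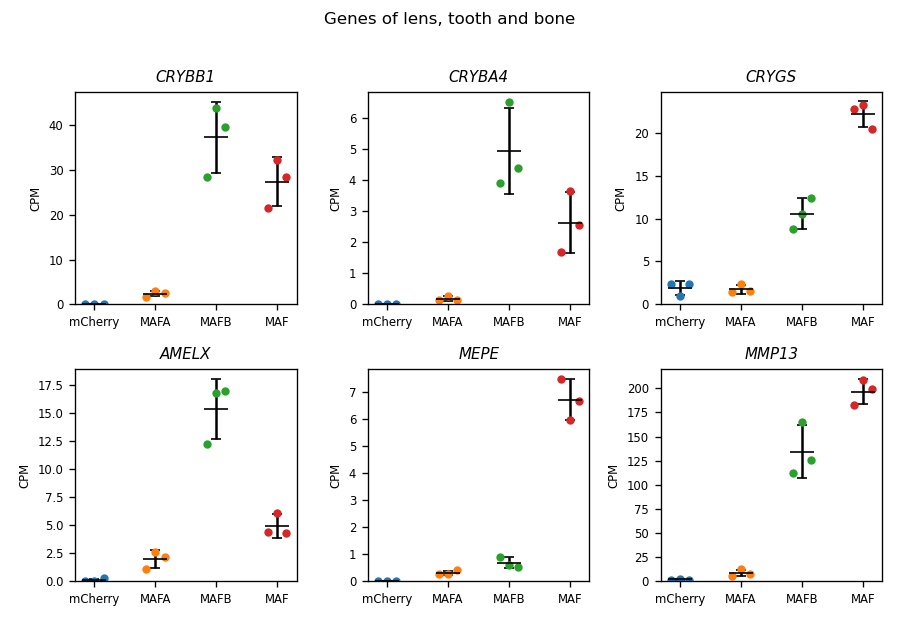
Normalised counts (CPM, vertical axis of each panel) of CRYBB1, CRYBA4, CRYGS, AMELX, MEPE and MMP13 in the mCherry control, MAFA, MAFB and MAF groups, where points are libraries, horizontal lines are group means and bars are SD (n = 3). CRYBB1 lay at a mean of 0.0477 CPM in the control and 37.3 CPM with MAFB, and MEPE at 6.72 CPM with MAF.

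MYH1 (log2 fold change -1.66, SE 0.26), MYH2 (-0.48, SE 0.07), MYH3 (-0.79, SE 0.12), MYH7 (-1.33, SE 0.15), MYH7B (-1.32, SE 0.12) and MYH6 fell with MAF, and MYH8 was at 0.19 (adjusted p = 0.186, 0.000152 with no filter and 0.0268 with only the groups compared). On limma's scale of log2 of the value plus a pseudocount, the log2 fold change of MYH4 was 1.79 with MAFA, 4.64 with MAFB and 4.10 with MAF at a pseudocount of 10, and 4.80, 7.98 and 7.42 at 0.1. The adult fast list held 1 rise and 2 falls of 3, also adjusted over the list alone, with a median of -0.48, a mean of 1.36 and an upward camera test (adjusted p = 0.403). Of the 6 other sarcomeric myosins 4 fell, and 1 was higher and 4 lower adjusted over the list alone (camera, adjusted p = 0.00645, adjusted p = 0.28 with an estimated correlation, and adjusted p from 0.0653 to 0.0791 in the 5 limma settings). As a share of all sarcomeric myosin heavy chain counts, MYH3 held 86.5% ± 0.25 in the control, 83.8% ± 0.32 with MAFA, 80.6% ± 0.27 with MAFB and 80.6% ± 0.79 with MAF (SD, n = 3). MYH8 held 8.12% ± 0.27, 12.3% ± 0.2, 16.2% ± 0.13 and 14.9% ± 0.32 in the same order. MYH4 held 0.00268% ± 0.0023, 0.0626% ± 0.035, 0.428% ± 0.1 and 0.365% ± 0.1. The share of MYH2 was 1.06% ± 0.12, 1.08% ± 0.22, 1.04% ± 0.14 and 1.24% ± 0.31, so its fall in CPM was not a fall among these genes. For MYH1 the share was lower with each factor, at 0.0715% ± 0.011 in the control and 0.0374% ± 0.012, 0.0459% ± 0.0047 and 0.0358% ± 0.0072.

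**Figure D2:**
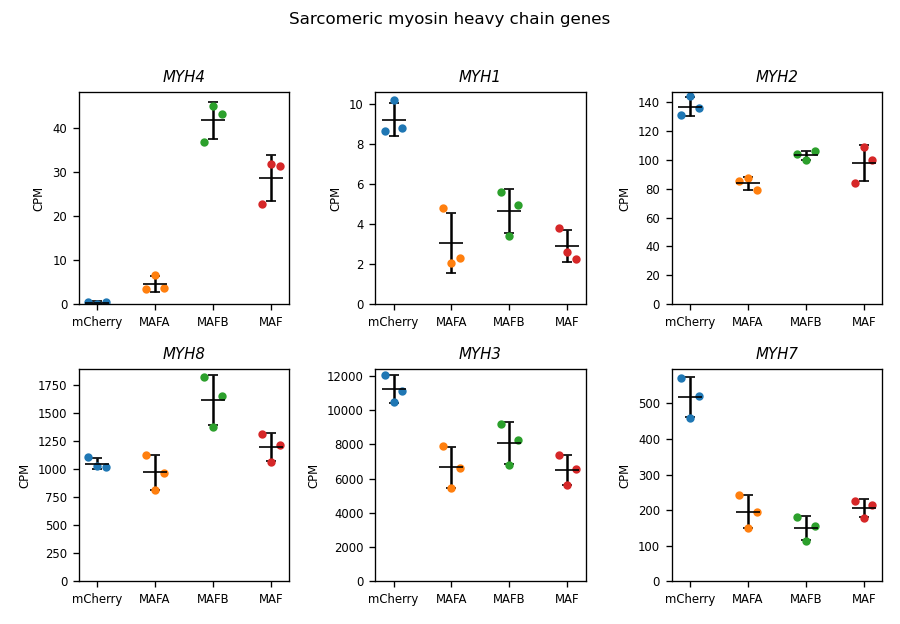
Normalised counts (CPM, vertical axis of each panel) of MYH4, MYH1, MYH2, MYH8, MYH3 and MYH7 in the mCherry control, MAFA, MAFB and MAF groups, where points are libraries, horizontal lines are group means and bars are SD (n = 3). MYH4 was at a mean of 0.358 CPM in the control and 4.66, 41.8 and 28.7 CPM with MAFA, MAFB and MAF, and MYH1 was highest in the control at 9.21 CPM.

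Slow-fibre genes fell in 9 of 10 members with MAF, also adjusted over the list alone (camera, adjusted p = 1.69e-10, and adjusted p = 0.138 with an estimated correlation). Embryonic muscle genes fell in 7 of 8, also adjusted over the list alone (camera, adjusted p = 0.000115, and adjusted p = 0.306 with an estimated correlation). Of 18 genes of fusion and mature structure 1 rose and 12 fell, also adjusted over the list alone (camera, adjusted p = 1.68e-08, and adjusted p = 0.28 with an estimated correlation), with ACTA1 at -1.15 and XIRP1 at -1.12. Of 10 neuromuscular junction genes 1 rose, or 0 without control library 3 or MAF library 3, and 8 fell, also adjusted over the list alone (camera, adjusted p = 9.25e-05, and adjusted p = 0.28 with an estimated correlation). Excitation-contraction coupling genes fell in 7 of 14, with 1 higher and 9 lower adjusted over the list alone (camera, adjusted p = 0.0101, and adjusted p = 0.457 with an estimated correlation). Of 11 fast-fibre genes 6 rose and 5 fell, also adjusted over the list alone (camera, adjusted p = 0.919). MYOZ1 rose 3.28-fold, ACTN3 3.39-fold and PVALB, the calcium buffer of fast fibres, 2.79-fold to 8.95 ± 1.88 CPM, while TNNI2 fell by 0.98. Of 21 myogenic and fibre-type regulators 2 rose, or 1 without control library 1 or MAF library 2 or 3, and 8 fell, also adjusted over the list alone (camera, adjusted p = 0.0299, 0.0517 without MAF library 1, adjusted p = 0.28 with an estimated correlation, and adjusted p from 0.0638 to 0.0693 in the 5 limma settings). Of 17 genes of fatty acid oxidation and its regulators 8 rose and 1 fell, or 2 without MAF library 2, also adjusted over the list alone (camera, adjusted p = 0.0829, 0.0448 without control library 1, and from 0.00381 to 0.0463 in limma, with no filter and with the stricter filter), and PPARGC1A rose 2.35-fold. Of 29 glycolysis and glycogen genes 12 rose and 9 fell, 12 and 10 adjusted over the list alone (camera, adjusted p = 0.441).

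Cell cycle genes fell in 15 of 20 members with MAF and 1 rose, 16 and 1 adjusted over the list alone (camera, adjusted p = 6.11e-08, and adjusted p = 0.00957 with an estimated correlation), TOP2A from 103 ± 3.88 to 51.5 ± 7.36 CPM. The rise, of MCM6, ended without control library 2 (adjusted p = 0.0662). Of 8 neuronal genes 1 rose and 6 fell, also adjusted over the list alone (camera, adjusted p = 0.000564, and adjusted p = 0.0302 with an estimated correlation), with GAP43 at -1.35. The rise, of SNAP25, ended without any 1 of the 6 libraries (adjusted p from 0.0532 to 0.193). Interferon response genes rose in 7 of 19, 8 adjusted over the list alone (camera, adjusted p = 0.0309, 0.0527 without MAF library 2, 0.0625 with the stricter filter, and adjusted p = 0.46 with an estimated correlation). That call also ended with the replicate block. CXCL10, a chemokine, had 111 counts against 3 (ratio 37.1, interval 12.4 to 183, and a fitted log2 fold change of 5.04, or 8.21 without control library 3). Unfolded protein and amino acid stress genes fell in 7 of 16, 10 adjusted over the list alone (camera, adjusted p = 0.0101, and adjusted p = 0.306 with an estimated correlation). Of 6 macrophage genes 3 rose and 1 fell, 4 and 1 adjusted over the list alone (camera, adjusted p = 0.0224, adjusted p = 0.138 with an estimated correlation, and adjusted p from 0.0625 to 0.0749 with no filter, the stricter filter and only the groups compared). That call also ended with the replicate block. CD68 had 54 counts against 2 (ratio 27.1, interval 7.15 to 229), and F13A1 fell by 2.14. Of 12 fibroblast and matrix genes 6 rose and 3 fell, 7 and 3 adjusted over the list alone (camera, adjusted p = 0.763), with PDGFRA at 0.28 and DCN at -0.76. Of 7 smooth muscle genes 2 rose, or 1 without control library 3 and 0 without MAF library 2, and 5 fell, also adjusted over the list alone (camera, adjusted p = 0.0115, adjusted p = 0.306 with an estimated correlation, and adjusted p from 0.0549 to 0.0618 in the 5 limma settings). Median, mean and test differed in sign for the NRF2 targets (-0.01, 0.10 and down).

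**Figure D3:**
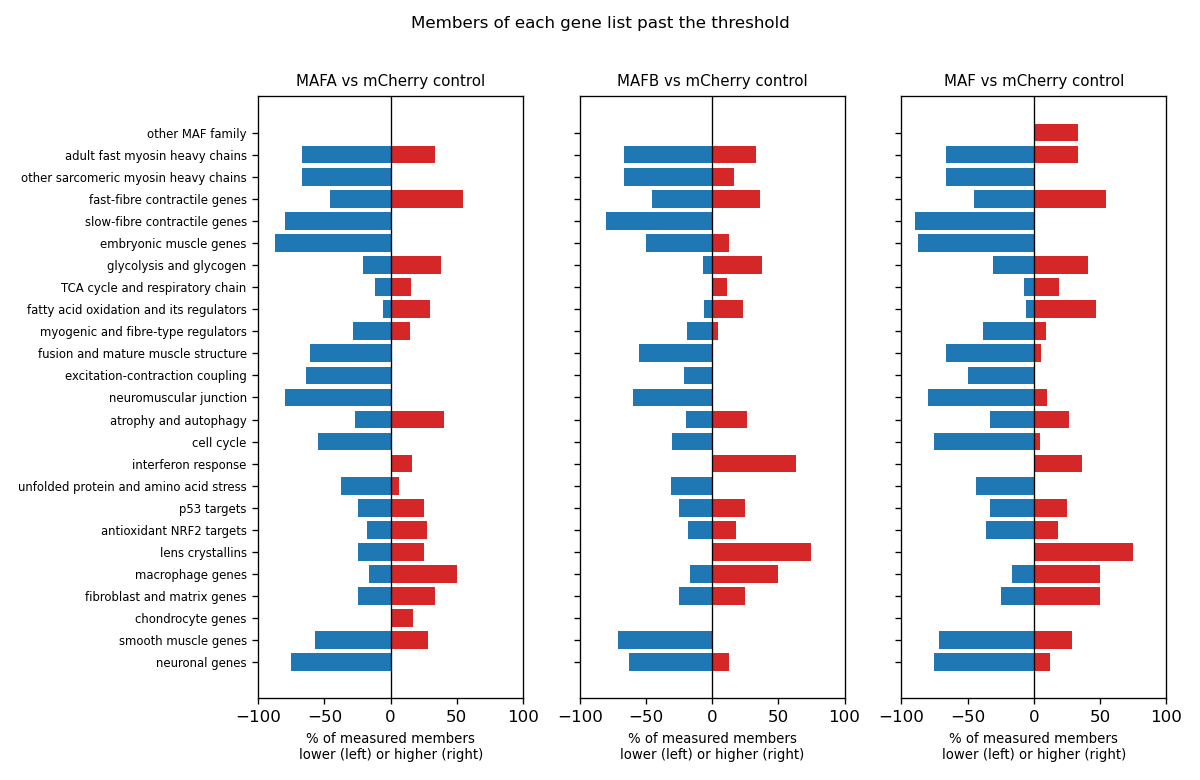
Percent of the measured members of each gene list (horizontal axis) that passed the threshold lower (blue, to the left) or higher (red, to the right) than the mCherry control, in a panel each for MAFA, MAFB and MAF. Slow-fibre contractile genes extended to the left in each panel, with 8, 8 and 9 of 10 members lower, and interferon response genes to the right, with 3, 7 and 12 of 19 higher with MAFA, MAF and MAFB.

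The responses to the 3 factors overlapped. Higher with all of them were 827 genes and lower with all 800, against 25.9 and 20.1 for independent lists. Simulated data with unchanged groups and shared controls gave at most 0. No gene was changed there and almost none was called. That value therefore cannot show how far shared controls raise the overlap of changed genes. MAFA and MAF shared 1460 rises and 1404 falls, MAFB and MAF 998 and 921, and MAFA and MAFB 879 and 832, while opposite changes were seen for 23, 5 and 10 genes. Over 11153 genes the covariance of log2 fold changes was 0.139 for MAFA and MAF, 0.128 for MAFB and MAF and 0.097 for MAFA and MAFB. In 20 simulated data sets it was 0.00729, 0.00729 and 0.00745, which leaves 0.132, 0.121 and 0.0895. The covariance grows with the size of the changes. By correlation MAFB and MAF were closest, at 0.878, with 0.853 for MAFA and MAF and 0.798 for MAFA and MAFB. The simulated correlations were 0.489, 0.491 and 0.496 in that order. The control libraries are too few to split, so part of the excess over independent lists may come from the shared controls. The F test over the 4 groups passed 4485 genes (32.4%).

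The next comparison set MAFA against MAFB. MYH4 was lower with MAFA (log2 fold change -3.16, SE 0.20, adjusted p = 9.51e-09), as were CRYBB1 (-3.96, SE 0.24, adjusted p = 5.28e-09), CRYBA4 (-4.62, SE 0.50, adjusted p = 3e-05), MMP13 (-3.95, SE 0.17, adjusted p = 7.05e-11) and GRIA2 (-3.85, SE 0.32, adjusted p = 5.45e-07). MYH8 was lower too, at -0.74 (SE 0.10, adjusted p = 0.000186). BMP5, a bone morphogenetic protein gene, was higher with MAFA (2.59, SE 0.50, adjusted p = 0.00316), and this moved to 1.98 without MAFB library 1 and 3.26 without MAFB library 3. In all, 1050 genes passed, 572 higher and 478 lower with MAFA, and 98 differed at least 2-fold, 32 higher and 66 lower. The count was 689 without MAFA library 2, 634 without MAFA library 3 and 613 without MAFB library 3, and the genes higher with MAFA numbered 381 without MAFB library 1. Of 1984 genes past the threshold with MAFA and not with MAFB, 473 differed between these groups, and of 440 past it with MAFB and not with MAFA, 108 did.

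Of 4 crystallins 3 were lower with MAFA than with MAFB, also adjusted over the list alone (camera, adjusted p = 1.53e-20, and adjusted p = 0.000258 with an estimated correlation). Of 3 adult fast myosins 2 were lower, 3 adjusted over the list alone (camera, adjusted p = 1.1e-10, and adjusted p = 0.00161 with an estimated correlation). MYH2 did not pass without MAFA library 3 (adjusted p = 0.0939) or MAFB library 3 (0.0764). Neuronal genes were lower in 3 of 8, 4 adjusted over the list alone (camera, adjusted p = 2.56e-05, and adjusted p = 0.0136 with an estimated correlation). Interferon response genes were lower in 7 of 19, or 4 without MAFA library 3, and 11 adjusted over the list alone (camera, adjusted p = 2.98e-08, and adjusted p = 0.119 with an estimated correlation). Embryonic muscle genes were lower in 4 of 8, 6 adjusted over the list alone (camera, adjusted p = 1.5e-05, and adjusted p = 0.307 with an estimated correlation), and excitation-contraction coupling genes in 6 of 14, 7 adjusted over the list alone (camera, adjusted p = 0.000264, and adjusted p = 0.317 with an estimated correlation). In these last lists 2 and 3 genes were lower without MAFA library 2 or 3 or MAFB library 1 or 3. Median, mean and test differed in sign for the delivered factors (-0.03, 1.35 and up, a test that turned or ended in limma, DESeq2, with no filter and without MAFB library 1, with adjusted p from 0.138 to 0.929), the unfolded protein list (0.04, 0.02 and down) and the atrophy list (0.02, -0.05 and down).

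Against MAF, MAFA again gave less MYH4 (log2 fold change -2.62, SE 0.21, adjusted p = 1.98e-07), a difference that missed the threshold only in limma with a pseudocount of 0.1 (adjusted p = 0.104). MMP13 (-4.51, SE 0.17, adjusted p = 3.13e-12), MEPE (-4.32, SE 0.34, adjusted p = 5.5e-07) and KL (-4.70, SE 0.43, adjusted p = 1.21e-06) were lower with MAFA, KL at -5.29 without MAFA library 1. C2CD4A had 3 counts with MAFA against 105 with MAF (ratio 35.2, interval 11.7 to 173), and its fitted log2 fold change moved from -4.96 to -5.82 without MAFA library 2. SPOCD1 (1.72, SE 0.24, adjusted p = 0.000138) and STC1, the hormone stanniocalcin (1.53, SE 0.12, adjusted p = 9.07e-08), were higher with MAFA. In all, 965 genes passed, 356 higher and 609 lower with MAFA, and 147 differed at least 2-fold. The count was 612 without MAFA library 3, 604 without MAF library 2 and 623 without MAF library 3, and with no filter 540 genes were higher with MAFA. Of 818 genes past the threshold with MAFA and not with MAF, 146 differed between these groups, and of 1506 past it with MAF and not with MAFA, 353 did. All 4 measured crystallins were lower with MAFA, also adjusted over the list alone (camera, adjusted p = 9.04e-25, and adjusted p = 0.000141 with an estimated correlation). Macrophage genes were lower in 2 of 6, or 1 without MAF library 2 or 3 or any 1 MAFA library, and 3 adjusted over the list alone (camera, adjusted p = 0.00346, and adjusted p = 0.058 with an estimated correlation). Of 3 adult fast myosins 1 was lower, or 2 without MAF library 1, and 2 adjusted over the list alone (camera, adjusted p = 3.35e-05, adjusted p = 0.0188 with an estimated correlation, and adjusted p from 0.133 to 0.254 in 4 limma settings). Cell cycle genes were higher in 4 of 20, also adjusted over the list alone (camera, adjusted p = 0.00735, 0.0519 without MAF library 2, and adjusted p = 0.11 with an estimated correlation). That count was 0 without MAFA library 1 or MAF library 2 or 3, 1 without MAFA library 2 or 3 and 2 without MAF library 1. Of the 3 delivered factors 1 was higher and 2 lower, also adjusted over the list alone (camera, adjusted p = 0.0112, and adjusted p = 0.224 with an estimated correlation). That test turned or ended without MAF library 1 (adjusted p = 0.263), MAF library 2 (0.841) or MAF library 3 (0.0923) and in limma, DESeq2 and with no filter (0.254 to 0.686). Median, mean and test differed in sign for the delivered factors (-0.89, 1.17 and up), the myogenic list (0.06, -0.01 and up), the glycolysis list (-0.00, -0.04 and up), the chondrocyte list (-0.01, 0.07 and up) and the list of fusion and mature structure, with a median of -0.02 and an upward test.

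The last comparison set MAFB against MAF. GADL1, a decarboxylase gene, was higher with MAFB (log2 fold change 4.23, SE 0.39, adjusted p = 1.44e-06), with 7.13 ± 1.2 CPM against 0.374 ± 0.224 CPM. KL (-5.44, SE 0.47, adjusted p = 6.49e-07) and MEPE (-3.24, SE 0.29, adjusted p = 2.34e-06) were lower with MAFB, KL at -6.62 without MAFB library 1. DPT, the matrix gene dermatopontin, had no count with MAFB and was at least 15.2-fold lower. BHMT had 1 count against 38 (ratio 37.7, interval 6.38 to 1530), and its fitted log2 fold change moved from -4.79 to -6.67 without MAFB library 3. MYH4 was higher with MAFB at 0.54 (adjusted p = 0.0211), which ended without MAFB library 2 (adjusted p = 0.0706), MAFB library 3 (0.0924) or MAF library 1 (0.0865) and in 5 limma settings (adjusted p up to 0.782). MYH8 was at 0.43 (adjusted p = 0.0101), which ended without MAFB library 1 (adjusted p = 0.0532) or MAF library 2 (0.0608) and in 2 limma settings and robust edgeR (adjusted p up to 0.178). In all, 1380 genes passed, 558 higher and 822 lower with MAFB, and 139 differed at least 2-fold. The count was 896 without MAF library 2, and the genes higher with MAFB numbered 338 without MAFB library 3 and 355 without MAF library 3. Of 237 genes past the threshold with MAFB and not with MAF, 60 differed between these groups, and of 2469 past it with MAF and not with MAFB, 653 did. Embryonic muscle genes were higher with MAFB in 4 of 8 members, or 0 without MAFB library 1 or MAF library 2 and 1 without MAFB library 3 or MAF library 3, and 6 adjusted over the list alone (camera, adjusted p = 0.000702, and adjusted p = 0.61 with an estimated correlation). Myogenic and fibre-type regulators were higher with MAFB in 7 of 21 members, or 3 without MAFB library 1 and 4 without MAF library 3, with 8 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.000702, and adjusted p = 0.151 with an estimated correlation). Of 20 cell cycle genes 6 were higher and 1 lower, 10 and 1 adjusted over the list alone (camera, adjusted p = 0.00012, and adjusted p = 0.0639 with an estimated correlation). Of 19 interferon response genes 4 were higher, or 2 without MAFB library 2, and 1 lower, 9 and 1 adjusted over the list alone (camera, adjusted p = 0.000702, and adjusted p = 0.433 with an estimated correlation), and neuronal genes were higher in 3 of 8, 4 adjusted over the list alone (camera, adjusted p = 0.00105, and adjusted p = 0.0639 with an estimated correlation). Median, mean and test differed in sign for the NRF2 targets (0.02, -0.03 and up) and the crystallins (0.07, -0.01 and down).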

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

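The contrasts between factors were set before the data were examined, but the genes shown here were picked by the same tests. Their p-values are therefore no further support. Only the named genes were screened, while over all genes 10 changed in opposite directions for MAFA and MAFB, 23 for MAFA and MAF and 5 for MAFB and MAF. These results stand out because the factors moved a gene in opposite directions and edgeR's test of the difference passed.

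PDGFRA, a growth factor receptor gene of mesenchymal cells, fell by 0.19 on the log2 scale with MAFA (adjusted p = 0.0267) and rose by 0.23 with MAFB and 0.28 with MAF. The difference was -0.42 between MAFA and MAFB (edgeR, adjusted p = 0.000186) and -0.47 between MAFA and MAF (edgeR, adjusted p = 4.7e-05). The rise with MAFB ended without control library 1 (adjusted p = 0.0645), without control library 3 (0.0548) and in limma without a trend (0.0613). PDGFRA was at 190 ± 18.1 CPM in the control, 166.9 ± 6.68 with MAFA, 223.5 ± 5.68 with MAFB and 230.3 ± 12.8 with MAF (SD, n = 3).

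As the design implies for the gene delivered in the MAF group, MAF differed by -2.48 between MAFA and MAF (edgeR, adjusted p = 3.79e-13). It rose by 2.20 with MAF and fell by 0.27 with MAFA, a fall that ended without control library 1 (adjusted p = 0.0726), control library 3 (0.0648), MAFA library 2 (0.0557) or MAFA library 3 (0.0505).

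STC1 rose by 0.74 with MAFA (edgeR, adjusted p = 3.72e-05) and fell by 0.79 with MAF (edgeR, adjusted p = 6.59e-05), a difference of 1.53 (edgeR, adjusted p = 9.07e-08). STC1 was at 35.3 ± 1.59 CPM in the control, 58.8 ± 7.12 with MAFA, 30.8 ± 4.03 with MAFB and 20.3 ± 3.38 with MAF (SD, n = 3).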

How the results depend on the processing

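Every alternative was planned before the data were examined. The number of genes past the threshold stayed within 1.5 times against the control except at 2-fold, which left 424 with MAFA, 278 with MAFB, 650 with MAF, 732 in the F test and 182 shared by the 3 factors, and except that falls with MAFB numbered 674 without MAFB library 3 and 650 in DESeq2. Between factors (MAFA and MAFB, MAFA and MAF, MAFB and MAF) 2-fold left 98, 147 and 139, DESeq2 gave 606, 607 and 865, and limma without a trend 582, 535 and 805. With no filter 540 genes were higher with MAFA than with MAF. Leaving out 1 library gave 613 to 1049, 604 to 962 and 896 to 1436 between factors, 2974 to 3437 with MAFA, 1527 to 1972 with MAFB, 3566 to 4192 with MAF, 3696 to 4475 in the F test and 1234 to 1644 shared. Those fits hold fewer libraries, and for the other alternatives the cause was not tested. The F test has no value for only the groups compared.

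The replicate block gave 2003, 1770 and 2297 genes between factors and 4470, 3008 and 5131 against the control. Deviations from the group means correlated at 0.157 to 0.234 between libraries numbered 1, 0.163 to 0.24 for number 2 and -0.02 to 0.047 for number 3, against at most 0.018 between different numbers. Not every pair passed 0.1, the bound set for pairing, so the main fit did not pair the libraries. For number 3 that bound could not decide. A library midway between numbers 1 and 2 of its group deviates little, so its correlations lie near 0 even under pairing. The main fit may therefore have missed calls through a replicate effect that it leaves out. The data, though not the design, point towards pairing. By its single highest correlation each of the 12 libraries went best with its own number, and by the mean 11 did, but not control library 3 (-0.0027 with number 3 and 0.0041 with number 2). The third principal component (9.3% of the variance) put number 1 highest and number 2 lowest in each of the 4 groups, from 5.88 to 17.04 for number 1, -6.26 to 5.86 for number 3 and -19.59 to -3.12 for number 2. The block moved the delivered factors, MAFB against MAF, to the other direction (camera, unadjusted p = 0.00473). It gained 18 of 352 values of named genes and ended none. It gained 4 list calls, fast-fibre (adjusted p = 0.0257) and unfolded protein genes (0.025) with MAFA and, for MAFB against MAF, adult fast myosins (0.0381) and structural genes (0.0102). It ended 2, interferon response (0.0562) and macrophage genes (0.0639) with MAF.

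Values of named genes ended in 167 of 352 cases at 2-fold, in 171 of 2112 with a library left out, where 16 were gained, and in 148 of 4154 in other settings, where 43 were gained. List calls ended in 52 of 156 cases with an estimated correlation. The totals in this paragraph count every test, also those not past the threshold in the main fit, which cannot end. The share of calls that ended is therefore higher. With an estimated correlation most list calls ended, and those that held are named with the MAFA results. With fry 12 of 156 ended and 20 were gained. In other settings 92 of 1866 ended and 34 were gained, and with a library left out 34 of 936 ended and 17 were gained. A list changed direction in 3 comparisons besides the block, and the cause was not tested. For the adult fast myosins, MAFB against the control, camera's unadjusted p was 0.828 in limma, also without a trend or robust, and 0.573 at a pseudocount of 0.1. For the delivered factors, MAFA against MAFB, it was 0.929 and 0.906 in those settings and 0.589 in DESeq2. For the same list, MAFA against MAF, it was 0.126 and 0.117, 0.182 at a pseudocount of 10, 0.486 in DESeq2 and 0.133 with no filter, and the direction also changed without MAF library 1 (0.0709) or MAF library 2 (0.814). Over all fits of this list with a library left out the p ran from 1.72e-19, in the main direction, to 0.814. A sign change was counted only where a value was past the threshold in 1 of the fits, which left out 132 others. Depth limits genes near 1 CPM, which rest on about 7 counts per library.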

Other observations

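The tests of MAFA dose against MAF, of muscle-cell share, of reads shared with neighbouring myosins and of lens cells, the lists of glutamate receptor and mineralised tissue genes, and the 80% bound for other cell types were chosen after results were seen.

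GRIA4, a gene of AMPA-type glutamate receptors, rose by 3.69 (SE 0.32), 4.13 (SE 0.30) and 5.11 (SE 0.26) on the log2 scale with MAFA, MAFB and MAF, from 0.362 CPM to 4.93, 6.71 and 13.2 CPM. GRIA1 rose by 1.27, 1.19 and 3.01 (edgeR, adjusted p = 0.00333, 0.0101 and 2.5e-08), with MAFB not without control library 3 (adjusted p = 0.0607) or MAFB library 3 (0.0777), and GRIA3 was at -0.17, -0.55 and -0.11 (edgeR, adjusted p from 0.734 to 0.935). Of the kainate receptor genes GRIK2, GRIK4 and GRIK5 did not pass with any factor (edgeR, adjusted p from 0.126 to 0.95), and GRIK1, at -1.29, -1.21 and -1.11, passed with each (edgeR, adjusted p = 0.0136, 0.0301 and 0.0233). Without MAFA library 1, GRIK2 did pass with MAFA (log2 fold change -1.46, edgeR, adjusted p = 0.0298). The calls of GRIK1 ended without MAFA library 1 or 3 with MAFA (adjusted p = 0.0538 and 0.0649). They ended without control library 2 or 3 or MAFB library 1 or 3 with MAFB (0.0767, 0.0877, 0.133 and 0.0622) and without control library 2 or 3 or MAF library 2 or 3 with MAF (0.0595, 0.0658, 0.0876 and 0.0996). MMP9, a gelatinase gene, rose by 2.47 (SE 0.40), 4.25 (SE 0.32) and 4.02 (SE 0.33), from 2.69 CPM to 14.8, 51.2 and 43.1 CPM. RUNX2, a transcription factor gene of bone formation, rose by 0.89 with MAF (edgeR, adjusted p = 8.07e-05).

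MYH4 rose with each factor and lay lower with MAFA than with MAFB or MAF, as did 3 of 4 crystallins against MAFB and 4 of 4 against MAF. Reads shared with the neighbouring myosin genes would keep the ratio of MYH4 to MYH1, MYH2 and MYH8 together, but its log2 rose by 4.12 with MAFA, 6.61 with MAFB and 6.47 with MAF, against a control SD of 1.76, and MYH1 and MYH2 fell. A lower delivered dose of MAFA could weaken the response as a whole. The delivered transcript was at 322.5 to 405.5 CPM with MAFA, 336.9 to 436.1 with MAFB and 556.3 to 745.8 with MAF. The MAFB and MAF values include the cells' own transcripts (38.91 to 41.96 and 132.6 to 146 CPM in the control). In RNA MAFA thus overlapped MAFB and lay below MAF. CPM is not scaled to transcript length and protein was not measured, so these levels do not settle the dose. Over 4390 genes changed with MAF the median MAFA minus MAFB difference in the direction of the MAF response was 0.08 (0.029 to 0.124 over pairs of libraries). This median cannot decide on dose, because more of the genes changed with MAF were also called with MAFA (1460 rises and 1404 falls) than with MAFB (998 and 921). MAFA also had more calls in all, 3705 against 2161, so those counts do not rank likeness to MAF. A median above 0 can follow from the larger number shared alone. Against MAF the dose stays open too. Over 2160 genes changed with MAFB the median MAFA minus MAF difference in the direction of the MAFB response was -0.081 (-0.174 to 0.006 over pairs of libraries). A difference between the factors themselves may remain, as a hypothesis found and tested on the same data.

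Several genes of lens, tooth and bone rose from low levels, CRYBB1, AMELX and SPP1 among them. Cells of these types would bring their other abundant transcripts, but 8 of 10 transcripts of lens cells stayed below 10% of CRYBB1 in every factor group. So did 5 of 5 of osteoblasts or osteocytes against SPP1 and 4 of 5 of ameloblasts against AMELX. The bound first written asked this of every transcript, which was wrong for BFSP1, MIP and ENAM. They missed it but were at 3.33, 0.318 and 2.51 CPM in the control already and did not rise past the threshold. The 80% bound was set after that, and the lens and ameloblast counts only just meet it, so they decide little. With MAFA, CRYBB1 had 52 counts over the group and AMELX was at 1.96 CPM, so 10% of either lies near the counting floor. Of 8 mineralised tissue genes not seen when their list was made, 4 rose with MAF, exactly the least the test asked for, and 3 fell, but 3 rose without control library 1, MAF library 1 or MAF library 2, where ALPL did not pass (adjusted p = 0.13, 0.0556 and 0.135), and 2 fell without any 1 of the 6 libraries, where ENAM or PHEX did not (0.0626 to 0.17). With MAFA 3 rose and with MAFB 2, or 1 without control library 1 or MAFB library 2 or 3, and 1 fell with each, with MAFA 0 without control library 2 or MAFA library 1 or 3 and 2 without MAFA library 2. Over all genes 14% rose with MAFA, 8.3% with MAFB and 16.2% with MAF. With 8 genes, and falls beside the rises, the counts say little about a shared rise of the list.

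Of 69 genes on 6 muscle lists 46 fell with MAFA, 35 with MAFB, 46 with MAF and 35 with all 3 factors, but no camera call of these lists held with an estimated correlation (adjusted p from 0.0612 to 0.457). A lower share of muscle cells would lower every muscle gene, but 4 rose with all 3 factors (ACTN3, MYBPC2, ATP2A1 and MYOZ1), and fibroblast genes moved apart, 4 higher and 3 lower with MAFA, 3 and 3 with MAFB and 6 and 3 with MAF. Those counts fell to 2 higher with MAFA without control library 1 or MAFA library 2, and with MAFB to 1 higher without control library 1 or 3 and 1 lower without MAFB library 3. The rise of ACTN3 with MAFA ended without control library 1 (edgeR, adjusted p = 0.0812), MAFA library 1 (0.0622) or MAFA library 2 (0.0604), and after a correction for transcript length and GC content at least 97.8% of the falls stayed past the threshold. A change within the muscle cells may remain, and a part played by cell share stays open.

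The 6 libraries of a pair of groups have 10 splits into 3 and 3, too few for a share under 0.05. In edgeR fits of those 6 libraries the real split, 1 of 10 each time, passed 3617 genes for MAFA, 2150 for MAFB and 4364 for MAF against the control, 835 for MAFA against MAFB, 758 for MAFA against MAF and 1165 for MAFB against MAF. The highest of the other splits passed 0 in each, with up to 677, 870, 556, 1385, 1253 and 1322 genes at an unadjusted p under 0.05. For the F test, of 100 groupings 1, the real one, reached 4485 genes, so a chance assignment of the library labels is unlikely to give that count. Chance differences between cultures cannot be excluded this way, since the libraries of a group may come from 1 culture. The highest other passed 2179, and it kept the 3 libraries of 1 group together.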
